A study of Mus musculus with 6 samples.

How the data were processed

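The series holds RNA-seq of 6 samples of p53-deleted mouse embryonic fibroblasts, 3 with a control hairpin (shNT) and 3 with a hairpin against ARF (shARF). Groups and replicate numbers were taken from the titles, all of which also carry the tag neo. The labels give the genotype as WT beside a cell line described as p53-deleted; the text follows the cell line. Per the labels' protocols, hairpins were delivered by lentivirus, total RNA was extracted with a column kit, and libraries were made with a stranded kit that removes ribosomal RNA.

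The authors deposited 1 table of whole-number counts per gene, with 54752 rows named by versioned mouse Ensembl gene IDs. The submitters' processing notes name Trim Galore 0.4.1, HISAT2 2.1.0, SAMtools 0.1.19, Picard 2.13.2, StringTie 1.3.2 and DESeq2 1.34.0 and the build GRCm38, with no role or order. Which tool made the counts, the annotation release, the strand setting and any removal of duplicate reads are not given in the sources used here. If counting ignored strand, reads of overlapping and antisense genes are mixed; if duplicates were removed, the most abundant genes are understated. The table has 6 further columns that match no sample of this series, which were used in no step. In the shARF columns the sequencing index number differs from that in the titles (the columns run on from those of shNT), and columns were matched on group and replicate.

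Gene symbols, types and coordinates came from GENCODE release M21 (Ensembl 96, build GRCm38). Of the 54752 IDs, 54723 matched when the version was ignored and 53861 matched exactly; 29 rows without a symbol held 0.0029% of counts. A count above 0 in any library was found for 27864 rows. Mitochondrially encoded genes had a count of 0 in all libraries, so that list of the 36 was not tested. Where 2 IDs carry the symbol of a list member (Aldoa, Ddit3 and Rmrp), the ID with more counts was used; this was set after the files were read.

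Total counts per library were 40.3 to 47.0 M, so that 1 CPM stands for about 40 reads or more. For some genes the SD over 3 libraries lies under the counting error, so a small SD does not give the precision of a mean. Libraries of 1 group differed by more than counting noise (chi-square per gene 17.6 to 24.1, against 181 to 193 between groups), so no pair was treated as 1 library deposited more than once. Pearson correlations of log2 CPM were 0.987 to 0.99 within groups and 0.939 to 0.943 between groups.

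The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest) on the counts as deposited, with group as the sole term, TMM normalization and the filterByExpr defaults (minimum count 10, minimum total 15), two-sided, with Benjamini-Hochberg adjustment over 17128 genes and a threshold of 0.05. CPM are scaled by the TMM factors; means carry the SD over 3 libraries, and fold changes the standard error of the fit, computed with a prior count of 0.125. For a gene with no count in 1 group, the fold is a lower bound against 3 counts over that group, which covers counting error only. The target gene was also tested by an exact permutation test.

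Gene lists (36, with 1054 members, 1048 of them in the table) were fixed before the data were examined, as were the main test, the rule for named genes and most of the other analyses listed at the end. They cover the target locus, the PAF1 complex, p53, interferon, growth factor, cell cycle, ribosome and stress programs, markers of other cell types, and HOX, imprinted and sex-linked genes. Each of the 35 lists with at least 4 members tested was tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. No list passed with the estimated correlation. fry, which asks only whether members move on balance, was run as well.

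Named genes were Cdkn2a, Cdkn2b, Trp53 and the PAF1 complex; the 12 genes with the largest rise and the 12 with the largest fall among called genes with a mean of at least 5 CPM, no overlap between groups and a symbol that is not a predicted model; and from each list the 3 members with the smallest p. Sex-linked and HOX genes could be named where cultures are compared. Chromosomes were compared after seeing the data, with camera and with medians in windows of 10 Mb that hold at least 15 tested genes.

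Alternatives were DESeq2 1.42.0, other normalizations (RLE, upper quartile, library sizes alone), other filters (none, at least 1 CPM or at least 5 CPM in 3 libraries), limma-voom, a block on replicate number, structural RNAs left out, a threshold of 0.01 and each library left out in turn. After seeing the data, fold changes were also centred on the 10 Mb window, and sex chromosomes were left out. The steps were tested on simulated counts with the real means and depths of this comparison, with 200 genes changed. Over 16818 genes, edgeR recovered 53.7% of genes changed by 1.5-fold, 79.1% of those changed by 2-fold and 92.4% of those changed by 4-fold, and 5.66% of its calls were false. On the same simulated counts, 8.48% of the calls of limma-voom and 14.04% of those of DESeq2 were false. In the real data 56.4% of genes were called, a far larger share than was simulated, so these rates need not hold there.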

Results

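Mouse embryonic fibroblasts (MEFs), which are fibroblasts grown out of dissected mouse embryos, were used here in a line described as p53-deleted. They were infected with a lentivirus carrying a short hairpin RNA against ARF (shARF) or a negative control hairpin (shNT). Total RNA was depleted of ribosomal RNA and sequenced with a stranded kit, and the deposited values are whole-number counts per gene. There were 3 shARF and 3 shNT libraries, labelled as biological replicates. Total counts were 44.5, 47.0 and 40.3 M in shNT replicates 1, 2 and 3, and 46.3, 45.2 and 46.1 M in shARF replicates 1, 2 and 3. The first principal component of log2 CPM (counts scaled per 1 M counts of the library) held 76.3% of the variance and separated the groups. Along it, shNT libraries lay between -67.3 and -65 and shARF libraries between 65.7 and 66.8. The labels do not say whether replicates came from separate infections or cultures, so p-values measure the spread between these samples, which may be technical.

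The comparison of shARF with shNT asks, by the title of the series, how ARF acts on transcription once p53 is lost and how this relates to the PAF1 complex, an elongation factor that travels with RNA polymerase II. The hairpin's target, Cdkn2a (ENSMUSG00000044303.6; GRCm38 chromosome 4, 89274471 to 89294653, minus strand), encodes p19ARF and p16INK4a. Cdkn2a was at 231, 218 and 223 CPM in the shNT libraries and at 95.6, 103 and 107 CPM in the shARF libraries. The means were 224 ± 6.91 and 102 ± 5.57 CPM (SD, n = 3 each), so shARF held 45.5% of the shNT level (95% confidence interval 42.2 to 49%). The log2 fold change was -1.14 (SE 0.05, adjusted p = 2.52e-06, edgeR). The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Both products of Cdkn2a share exons and were counted as 1 gene, so the ARF transcript could not be separated from that of p16INK4a. The neighbours on chromosome 4 were higher in shARF. Genes over the whole chromosome were also higher on balance (median log2 fold change 0.20, in a comparison chosen after seeing the data). Cdkn2b, which encodes the cell cycle inhibitor p15INK4b, rose from 63.3 ± 3.81 to 96.9 ± 2.3 CPM (log2 fold change 0.61, adjusted p = 6.05e-05). Mtap rose from 183 ± 5.72 to 259 ± 7.52 CPM (0.50, adjusted p = 2.23e-05). Trp53 was at 2.26 ± 1.2 CPM in shNT and 2.61 ± 0.483 CPM in shARF (adjusted p = 0.674). Without shNT replicate 2 its log2 fold change of 0.73 passed the test (adjusted p = 0.0313, within a range of 0.0313 to 0.959 over the alternatives).

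Transcripts of the PAF1 complex differed little between the groups. Of its 6 genes, Leo1 rose from 44.8 ± 0.188 to 55.1 ± 0.554 CPM (log2 fold change 0.30, adjusted p = 2.62e-04) and Ctr9 fell from 101 ± 2.33 to 92.1 ± 1.58 CPM (-0.14, adjusted p = 0.00793). Paf1 (30.4 ± 0.419 and 30.1 ± 1.02 CPM), Cdc73 (69.3 ± 4.59 and 73.1 ± 1.98 CPM), Rtf1 (105 ± 2.19 and 103 ± 1.22 CPM) and Wdr61 (33.7 ± 3.17 and 34.8 ± 1.09 CPM) did not pass the test. With library sizes alone as the scaling, Rtf1 was called lower (-0.12, adjusted p = 0.0141, within a range of 0.0141 to 0.696 over the alternatives). With fold changes centred on their 10 Mb genomic window, an alternative chosen after seeing the data, Paf1 (0.24) and Cdc73 (0.49) were called higher. Their adjusted p were 0.00308 and 3.02e-04, with ranges up to 0.915 and 0.868 over the alternatives. These are transcript levels and say nothing of how the proteins assemble.

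**Figure D1:**
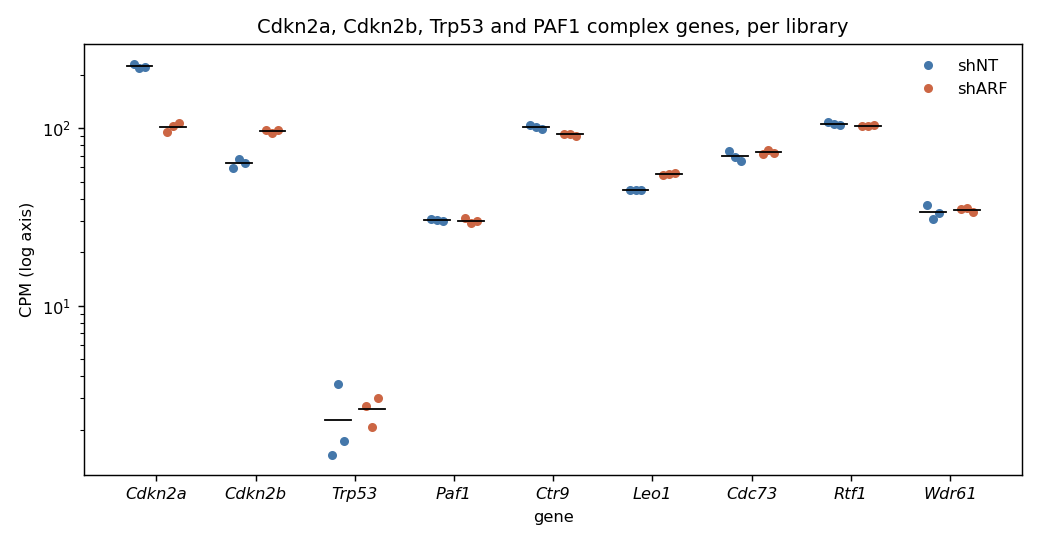
CPM of Cdkn2a, Cdkn2b, Trp53 and the 6 PAF1 complex genes on a log axis; each point is a library and each bar a group mean (3 shNT and 3 shARF libraries). Cdkn2a falls from a mean of 224 to 102 CPM, Cdkn2b is higher in all 3 shARF libraries, and the PAF1 complex genes lie close together in both groups.

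Many genes differed between the groups. Among 17128 genes tested, 4930 were higher and 4737 lower in shARF, which is 56.4% of genes, with a median absolute log2 fold change of 0.52 among those called. Changes of at least 2-fold were found for 1128 genes that rose and 1332 that fell, and changes of at least 4-fold for 482 and 505. The CPM of the groups did not overlap for 11065 genes (64.6%), against 10% by chance for 3 against 3. The groups were also apart for each gene given here with its CPM as risen or fallen. The share called depends on the genes tested and the tool. It was 33.7% of 27864 genes with no filter on low counts, and 41.1% of 22434 genes with DESeq2, where both differ. With library sizes alone, the split moved to 4023 higher and 5874 lower. With a filter of at least 5 CPM in 3 libraries, which tests 11230 genes, the changes of at least 2-fold numbered 528 higher and 578 lower.

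Several of the genes that rose most were close to absent in shNT. Gdf10, a secreted ligand of the TGF-beta superfamily, had no count in shNT and 35.9 ± 1.61 CPM in shARF, at least 1620-fold higher against a floor of 3 counts over the group. Foxa2, a forkhead transcription factor, went from no count to 12.4 ± 0.421 CPM, at least 562-fold higher. Myrf rose from 0.221 ± 0.0979 to 70.4 ± 5.65 CPM (log2 fold change 8.30, adjusted p = 3.88e-07), and Chl1, a cell adhesion molecule, from 1.3 ± 0.112 to 51.9 ± 5.86 CPM (5.32, adjusted p = 2.91e-07). Ptgis, which encodes prostacyclin synthase, rose to 33.6 ± 0.812 CPM, and Hand2, a transcription factor of limb, heart and sympathetic development, to 11.2 ± 0.344 CPM. The same rule named Upk3b, which rose from 0.0137 ± 0.0237 to 12 ± 0.353 CPM, and Car3, Frmd4b, Olr1, Dmrta2 and Moxd1, with log2 fold changes between 5.43 (Moxd1) and 8.27 (Car3).

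Genes that fell most included Grin3a, an NMDA receptor subunit, from 14.2 ± 0.599 to 0.0149 ± 0.0258 CPM (adjusted p = 1.35e-06), and Hunk, a kinase, from 38.7 ± 1.46 to 0.645 ± 0.0502 CPM (log2 fold change -5.90, adjusted p = 1.2e-07). Gjb2, a gap junction protein, fell from 34.9 ± 2.02 to 1.18 ± 0.0808 CPM (-4.89), and Gdf5, a ligand of joint development, from 12 ± 0.69 to 0.3 ± 0.0226 CPM (-5.32). Krt18, an intermediate filament gene of simple epithelia, fell from 12.7 ± 1.05 to 0.15 ± 0.13 CPM (-6.38, adjusted p = 2.72e-05). Angptl7, Slc17a6, Gpr149, Slc6a15, Slitrk5, Gria1 and Hoxb6 completed the set, with log2 fold changes between -8.39 (Angptl7) and -4.50 (Hoxb6).

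The groups also differed in genes that record the sex and body position of the cells. All 9 tested members of the sex-linked list were called, 5 higher and 4 lower, with the same counts adjusted over the list alone (set test adjusted p = 0.46). Xist, the RNA that coats the inactive X chromosome of female cells, fell from 387 ± 26.5 to 45.7 ± 7.49 CPM (log2 fold change -3.08). The 4 Y-linked genes rose. Kdm5d went from 0.782 ± 0.216 to 19.5 ± 0.623 CPM (4.64) and Ddx3y from 24.4 ± 1.6 to 85.3 ± 4.19 CPM (1.81). Eif2s3y went from 12.8 ± 0.693 to 38.3 ± 1.49 CPM (1.58) and Uty from 9.61 ± 0.482 to 21.7 ± 0.601 CPM (1.17). These Y-linked genes can share reads with X-linked paralogs, of which Kdm5c and Kdm6a fell (-0.70 and -0.63), Eif2s3x fell (-0.15) and Ddx3x rose (0.23).

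Of 33 HOX genes tested, 17 were higher and 15 lower, also adjusted over the list alone, and direction mostly followed the cluster. All 8 tested HoxB genes (chromosome 11) and all 6 tested HoxC genes (chromosome 15) fell, with medians of -3.85 and -3.10. All 8 tested HoxD genes (chromosome 2) rose, with a median of 2.41, as did 9 of 11 HoxA genes (chromosome 6, median 1.20). Hoxb9 fell from 103 ± 3.28 to 6.41 ± 0.563 CPM and Hoxc8 from 61.7 ± 1.62 to 4.89 ± 0.471 CPM, whereas Hoxd13 rose from 25.6 ± 1.7 to 127 ± 2.91 CPM. Genes in these clusters overlap one another and antisense transcripts, and the strand setting of the counting is not given in the sources used here. Because members went both ways, the set test gave an adjusted p of 0.756, toward lower, while the list's median was 0.46 and its mean -0.27.

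**Figure D2:**
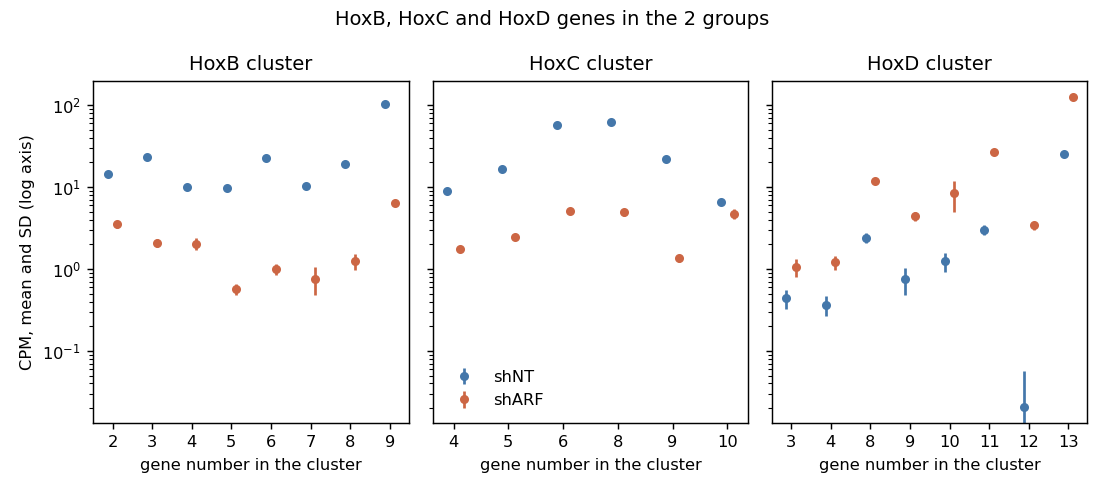
CPM of the HoxB, HoxC and HoxD genes by cluster, with the gene number along the horizontal axis and CPM on a log vertical axis; points are means and bars SD of 3 libraries per group. HoxB and HoxC genes are lower in shARF and HoxD genes higher, with Hoxb9 at 103 and 6.41 CPM and Hoxd13 at 25.6 and 127 CPM.

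Of the 35 gene lists tested, 6 passed camera with a preset correlation and none with an estimated one. Estimated correlations were 0.179 (interferon), 0.108 (collagen), 0.075 (ribosome biogenesis) and 0.04 (ATF4), above the preset 0.01. For hypoxia (-0.015) and smooth muscle (-0.055) they lay below it. Their unadjusted camera p still rose, from 9.62e-06 to 0.00687 and from 0.00655 to 0.0445. A higher correlation thus does not account for the loss of p in those lists. When the 6 libraries were split so that the groups were mixed, camera with the preset correlation called between 2 and 6 lists. Those mixtures were unequal, so part of the difference between shARF and shNT remained, and the lists called there may carry it. fry, which asks only whether members move on balance and does not compare them with other genes, passed for 28 of the 35 lists. Those included EMT (adjusted p = 6.92e-05), NF-kB (5.14e-05) and p53 target (4.35e-04) lists, all toward higher.

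Among the gene lists, genes of the ATF4 and amino acid stress response rose most uniformly: 26 of 30 were higher and 0 lower, with a median log2 fold change of 0.77 and the same counts adjusted over the list alone. The camera set test passed (adjusted p = 8.05e-14), but with an estimated correlation the adjusted p was 0.12. Trib3, a pseudokinase induced by ATF4, rose from 32.6 ± 0.761 to 132 ± 3.19 CPM (2.02, adjusted p = 1.59e-07), Slc7a3, a cationic amino acid transporter, from 1.3 ± 0.114 to 34.8 ± 3.16 CPM (4.74), and Sesn2 from 39 ± 2.36 to 154 ± 2.59 CPM (1.98). Atf4 itself was at 261 ± 65.1 CPM in shNT and 364 ± 128 CPM in shARF (adjusted p = 0.185). Hypoxia and glycolysis genes had 23 of 35 members higher and 4 lower, also adjusted over the list alone (median 0.47, adjusted p = 1.12e-04; adjusted p = 0.12 with an estimated correlation). Ero1l rose from 45.2 ± 1.21 to 270 ± 13 CPM (2.58), Slc16a3, a lactate transporter, from 4 ± 0.254 to 43.9 ± 2.45 CPM (3.45), and P4ha1, a collagen prolyl hydroxylase, from 180 ± 3.44 to 347 ± 6.13 CPM (0.95). These lists moved between libraries that also differed in Xist, Y-linked and HOX genes as above.

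Ribosome biogenesis and nucleolar genes had 44 of 58 members higher and 7 lower (45 and 7 adjusted over the list alone), with a median log2 fold change of 0.34 and no member changed by 2-fold. The set test passed (adjusted p = 5.25e-07; adjusted p = 0.39 with an estimated correlation). Ddx21 rose from 274 ± 7.3 to 438 ± 3.86 CPM (0.68), Bop1 from 109 ± 3.66 to 199 ± 5.68 CPM (0.87) and Gnl3, which encodes nucleostemin, from 61.4 ± 1.4 to 102 ± 2.88 CPM (0.74). Cytosolic ribosomal protein genes did not pass the set test (adjusted p = 0.529), with 14 of 80 higher and 19 lower (14 and 16 adjusted over the list alone). These genes can share reads with many pseudogenes. Interferon-stimulated genes had 29 of 58 members higher and 7 lower, also adjusted over the list alone (median 0.47, adjusted p = 0.00432; adjusted p = 0.508 with an estimated correlation). Many were at low levels: Trim30a rose from 0.096 ± 0.0133 to 3.04 ± 0.193 CPM and Ifi44 from 0.218 ± 0.0421 to 3.26 ± 0.797 CPM, while Tor3a rose from 21.1 ± 0.518 to 43.1 ± 0.864 CPM. Stat2 (-0.50), Trim25 (-0.65) and Eif2ak2 (-0.38), named after their values were seen, fell.

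Collagen and matrix glycoprotein genes had 28 of 50 members higher and 15 lower (28 and 18 adjusted over the list alone; median 0.23, adjusted p = 0.0382; adjusted p = 0.508 with an estimated correlation). That call was lost with a filter of at least 1 CPM in 3 libraries (adjusted p = 0.0639), and its adjusted p ranged from 0.0327 to 0.508 over the 10 alternatives in which lists were tested. With fold changes centred on 10 Mb windows, chosen after seeing the data, the list had a median of 0.15, with 26 members higher and 15 lower. Col4a2, a basement membrane collagen, rose from 238 ± 3.18 to 877 ± 9.36 CPM (1.88, adjusted p = 8.76e-08), Nid2 from 66.8 ± 1.47 to 229 ± 5.88 CPM (1.78) and Fbn1, which encodes fibrillin, from 1540 ± 17.5 to 3010 ± 37.4 CPM (0.97). Smooth muscle and myofibroblast markers had 2 of 14 members higher and 9 lower, also adjusted over the list alone (median -0.68, adjusted p = 0.0382; adjusted p = 0.39 with an estimated correlation). Actg2 fell from 39.8 ± 2.06 to 13.2 ± 1.5 CPM (-1.59), Lmod1 from 15.7 ± 0.592 to 6.79 ± 0.0561 CPM and Itga8 from 17.3 ± 0.0605 to 6.36 ± 0.85 CPM. Acta2 was at 1060 ± 29.4 and 1080 ± 32 CPM (adjusted p = 0.578). The same libraries differed in Xist, Y-linked and HOX genes.

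Lists tied to oncogenic transcription did not pass the set test against other genes. EMT and invasion genes had 29 of 54 higher and 15 lower (30 and 15 adjusted over the list alone; adjusted p = 0.0595), including Loxl2, a lysyl oxidase, from 154 ± 4.25 to 834 ± 20.9 CPM. That list passed without shNT replicate 3 (adjusted p = 0.0487), without shARF replicate 1 (0.0493) and without shARF replicate 3 (0.0454), within a range of 0.0454 to 0.508 over the 10 alternatives in which lists were tested. AP-1 and immediate early genes had 14 of 28 higher and 8 lower, also adjusted over the list alone (adjusted p = 0.42), with Fosl1 from 26 ± 0.904 to 56.3 ± 3.28 CPM. Fos (-0.74), Egr1 (-0.43) and Egr3 (-1.58), named after their values were seen, were among the lower members. ERK output genes had 15 of 28 higher and 7 lower (16 and 9 adjusted over the list alone; adjusted p = 0.379), with Ccnd1, which encodes cyclin D1, from 247 ± 10.8 to 663 ± 3.42 CPM and Il1rl1 from 428 ± 10.7 down to 151 ± 12.4 CPM. TGF-beta and YAP response genes had 14 of 25 higher and 5 lower (14 and 6 adjusted over the list alone; adjusted p = 0.0663). NF-kB targets and chemokines had 19 of 37 higher and 10 lower (19 and 11 adjusted over the list alone; adjusted p = 0.116), with Il33 from 2.61 ± 0.334 to 78.1 ± 4.39 CPM. Nfkb2 (-0.57) and Relb (-0.28), also named after their values were seen, were among the lower members. Elongation factors, Mediator and SWI/SNF genes had 9 of 33 higher and 13 lower, also adjusted over the list alone (adjusted p = 0.7), and no member changed by 2-fold.

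Cell cycle lists did not pass the set test against other genes, although fry, which asks whether members move on balance, gave S phase genes higher (adjusted p = 0.0221) and G2 and M phase genes lower (adjusted p = 0.0259). S phase genes had 13 of 42 higher and 15 lower, also adjusted over the list alone (adjusted p = 0.895). G2 and M phase genes had 8 of 40 higher and 16 lower (9 and 16 adjusted over the list alone; adjusted p = 0.309). Replication-dependent histone genes had 3 of 36 higher and 5 lower (2 and 1 adjusted over the list alone; adjusted p = 0.954). No member of these lists changed by 2-fold. In a p53-deleted line, p53 target genes had 20 of 39 higher and 10 lower, also adjusted over the list alone (adjusted p = 0.191), with Sesn2 and Sulf2 (72.1 ± 1.79 to 221 ± 7.11 CPM) higher and Perp (12.4 ± 0.219 to 1.21 ± 0.0725 CPM) lower. MHC class I and antigen processing genes had 11 of 18 higher and 6 lower (adjusted p = 0.315). H2-K1 rose from 18 ± 1.26 to 57.5 ± 0.605 CPM, and its near-identical relatives can share reads. Nlrc5, of the same list, fell from 3.72 ± 0.111 to 0.39 ± 0.0491 CPM. NRF2 targets had 10 of 25 higher and 6 lower (adjusted p = 0.309), cholesterol genes 4 of 25 higher and 11 lower (adjusted p = 0.0663), and small nuclear and structural RNAs 2 of 13 higher and 3 lower (adjusted p = 0.823). ER chaperone genes had 13 of 20 higher and 4 lower (adjusted p = 0.0664) and passed without shNT replicate 3 (adjusted p = 0.0487, within a range of 0.0487 to 0.508 over the 10 alternatives in which lists were tested). For these 5 lists the counts adjusted over the list alone were identical. The PAF1 complex and the target locus with p53 lists gave adjusted p = 0.895 each, with 1 of 6 higher and 1 lower and with 2 of 6 higher and 2 lower, also adjusted over the list alone.

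Markers of other cell types moved in mixed directions. Fibroblast markers had 4 of 13 higher and 6 lower (adjusted p = 0.139), with Pdgfra down from 502 ± 5.64 to 91.4 ± 2.23 CPM and Dcn, which encodes decorin, down from 198 ± 5 to 45.5 ± 3.55 CPM. Cartilage and bone markers had 1 of 9 higher and 6 lower (2 and 6 adjusted over the list alone; adjusted p = 0.0595), with Col2a1 down from 120 ± 2.19 to 9.04 ± 1.03 CPM and Acan down from 22.1 ± 0.986 to 1.88 ± 0.234 CPM. Without shNT replicate 2 (adjusted p = 0.0499), shARF replicate 1 (0.0493) or shARF replicate 3 (0.0454) the cartilage list passed, within a range of 0.0454 to 0.508 over the 10 alternatives in which lists were tested. Skeletal muscle markers had 4 of 7 higher and 1 lower (adjusted p = 0.171), and adipocyte markers 4 of 5 higher and 1 lower (adjusted p = 0.129). Endothelial markers had 3 of 8 higher and 4 lower (adjusted p = 0.895) and macrophage and blood markers 0 of 5 higher and 3 lower (adjusted p = 0.171). Epithelial markers had 6 of 9 higher and 1 lower (6 and 2 adjusted over the list alone; adjusted p = 0.256), and neural markers 4 of 8 higher and 1 lower (4 and 2 adjusted over the list alone; adjusted p = 0.716). Imprinted genes had 8 of 26 higher and 12 lower (adjusted p = 0.42), with Dlk1 down from 135 ± 6.6 to 7.42 ± 0.188 CPM and Peg10 down from 555 ± 13.9 to 214 ± 5.54 CPM, and Slc38a4 up from 91.3 ± 1.28 to 230 ± 2.79 CPM. For the fibroblast, muscle, adipocyte, endothelial, macrophage and imprinted lists the counts adjusted over the list alone were identical.

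**Figure D3:**
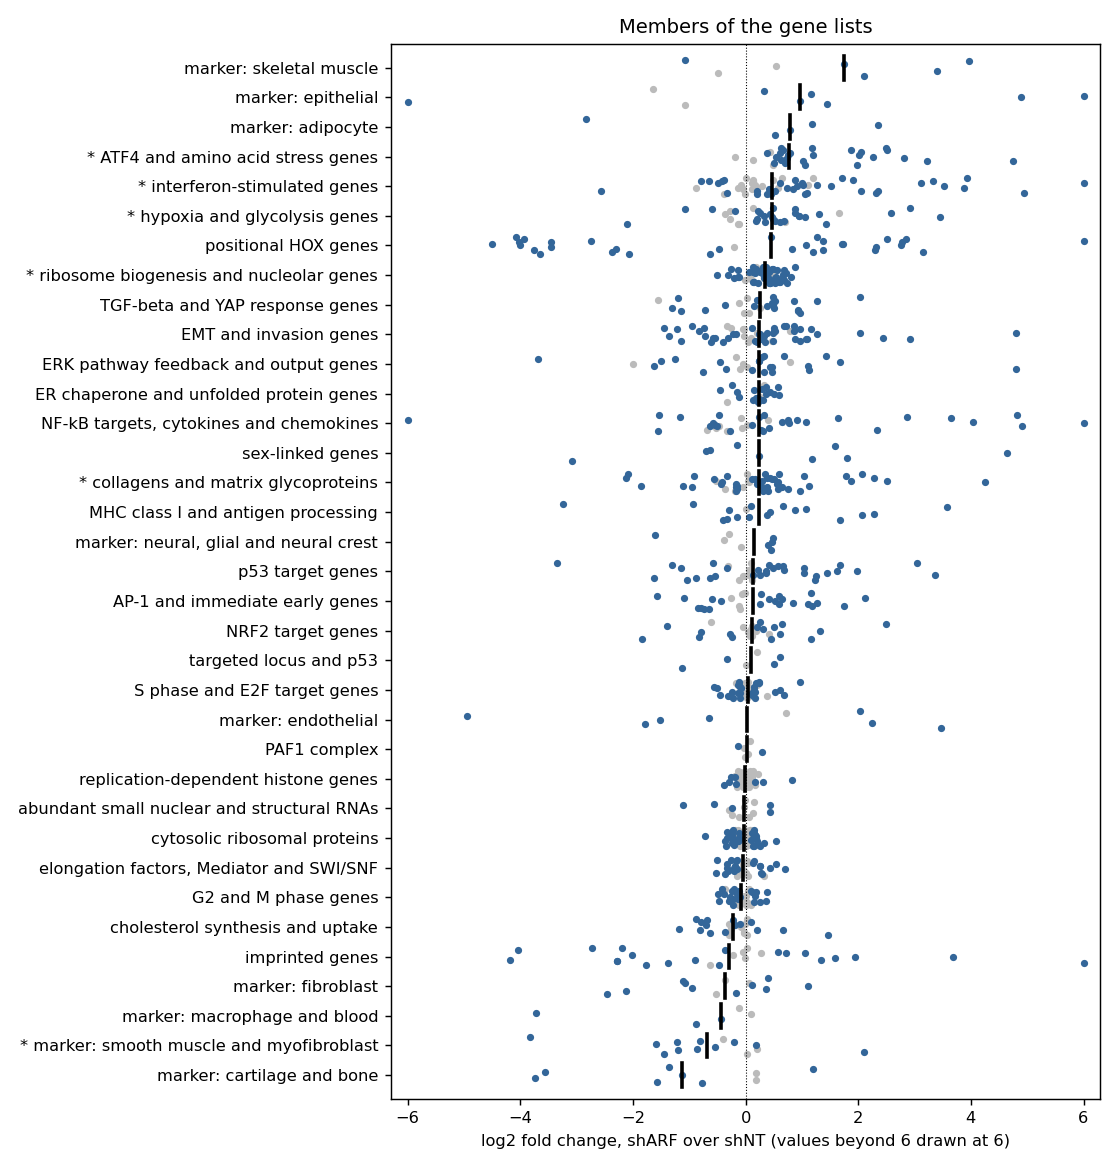
Log2 fold change (shARF over shNT) of the members of the 35 lists tested; blue points passed the gene test, grey points did not, black bars are list medians and an asterisk marks a list past the set test with a preset correlation. The ATF4 list lies to the right of 0 (median 0.77) and the HOX list splits into a higher and a lower part.

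Fold changes were also ordered along the genome, in a comparison chosen after seeing the data. Genes on chromosome 8 had a median log2 fold change of -0.27 (467 lower and 150 higher of 895), those on chromosome 12 of 0.27, on chromosome 14 of 0.20, on chromosome 4 of 0.20, on chromosome 9 of 0.13 and on chromosome 17 of -0.14, against -0.01 over all genes. Each of these 6 chromosomes passed camera with a preset correlation (adjusted p between 1.73e-05 for chromosome 8 and 0.0182 for chromosome 9) and with an estimated correlation (between 0.00412 and 0.0225). The X chromosome, with a median of -0.14, passed with the preset correlation (adjusted p = 0.0423) but not with the estimated one (adjusted p = 0.0504). Chromosome 5, with a median of 0.08, passed with the estimated correlation (adjusted p = 0.0283) but not with the preset one (adjusted p = 0.272). The shift of chromosome 8 was -0.27 ± 0.003 (SD over the 3 shARF libraries), and all 13 of its 10 Mb windows lay below 0. Cdkn2a fell on chromosome 4, where the other genes were on balance higher.

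**Figure D4:**
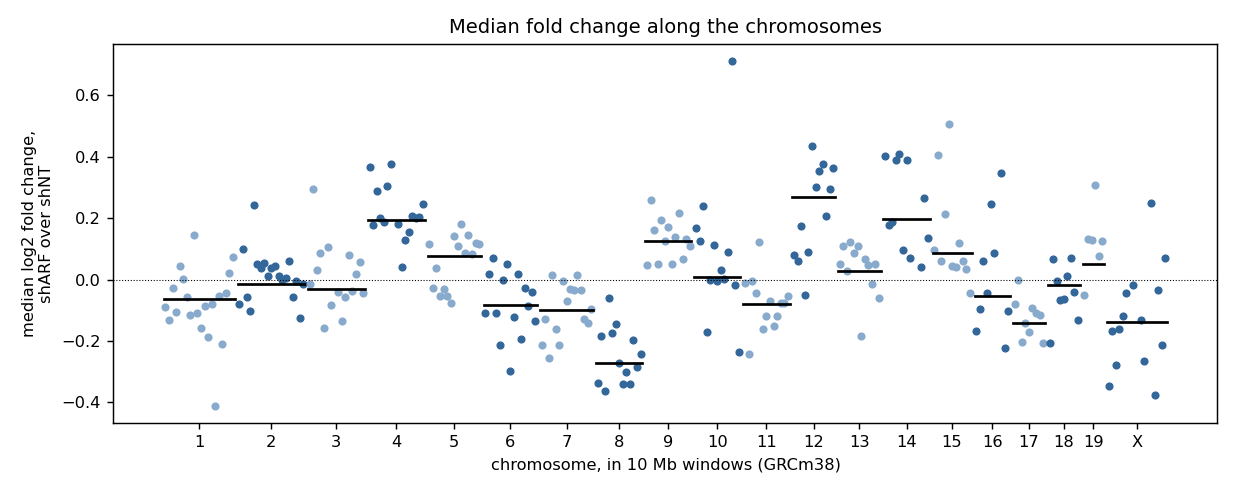
Median log2 fold change (shARF over shNT) in 10 Mb windows of at least 15 tested genes along the chromosomes (GRCm38), with chromosome medians as black lines. Chromosome 8 lies below 0 in all 13 windows and chromosome 4 above 0 in all 15.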

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

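The alternatives that centre on windows or leave out sex chromosomes were chosen after seeing the data. Counts of genes higher and lower in shARF stayed within 1.5 times the main counts under all 17 planned and both added alternatives. Leaving out each library in turn gave 4512 to 4738 higher and 4238 to 4440 lower. Called genes shared with the main test were 76.2% (at least 5 CPM) to 99.9% of 9667, and none changed sign except 98 after window centring. Changes of at least 2-fold fell to 528 higher and 578 lower with at least 5 CPM in 3 libraries, where fewer genes were tested. Cdkn2a kept its fall throughout, from -1.32 (window centring) to -1.09 (without shARF replicate 1). Of 130 named genes, Paf1 went from not called in the main test (-0.01, adjusted p = 0.802) to called higher with window centring (0.24, adjusted p = 0.00308). There the offset subtracts the lower median of its window. Cd14, counted among the lower macrophage markers, lost its call under several alternatives (adjusted p from 0.0127 to 0.0915 over all of them). Lists past the set test numbered 6, fell to 0 with an estimated correlation, and were 6 to 8 without single libraries; those gains, in the EMT, cartilage and ER chaperone lists, lay at adjusted p between 0.0454 and 0.0499. Replicate numbers did not pair the samples (correlations of deviations -0.09, -0.02 and 0.01). With the replicate block, 4604 genes were higher and 4309 lower and 4 lists passed, without the collagen (0.0663) and smooth muscle (0.0531) lists. Depth limits genes under about 1 CPM, such as many interferon-stimulated genes.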

Other observations

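The tests of Xist and Y-linked genes, and that of positional factors away from HOX clusters, were chosen after the result was seen; the others of chromosomes and HOX genes were written before their own results but after the patterns were noticed. Further genes tied to position in the body or to an imprinted locus differed between the groups, all named after their values were seen. Shox2, a limb transcription factor, fell from 67.8 ± 4.76 to 4.57 ± 0.286 CPM, and Irx1 and Irx2, which are neighbours on chromosome 13, fell from 45.2 ± 2.41 to 3.46 ± 0.0616 CPM and from 39.4 ± 0.685 to 4.41 ± 0.523 CPM. Irx1 and Irx2, and Meox2, were picked for naming from the list of positional factors weighed here for HOX genes, which had been fixed before the values of its members were seen. Meox2 rose from 0.0541 ± 0.0495 to 2.64 ± 0.318 CPM. In the imprinted Dlk1 and Meg3 locus on chromosome 12, Meg3 fell from 62.8 ± 5.02 to 9.51 ± 4.09 CPM and Rian from 147 ± 7.68 to 36.5 ± 1.43 CPM, together with Mirg (-2.28) and Rtl1 (-4.05), although the median of the chromosome was higher.

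Several further genes rose from no count in shNT: Upk1b to 9.58 ± 0.61 CPM (at least 434-fold higher), Lrrn4 to 8.91 ± 0.615 CPM (at least 404-fold), Aldh1a2 to 6.85 ± 0.076 CPM (at least 311-fold) and Muc16 to 3.35 ± 0.271 CPM (at least 152-fold). Wt1 rose from 0.102 ± 0.126 to 9.54 ± 0.443 CPM. Msln fell from 84.2 ± 1.63 to 54.4 ± 1.37 CPM. These genes were chosen after their values were seen and were in no list tested.

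Chromosome-wide shifts were not removed by a regression of fold change on GC content, exonic length and mean expression, which left the median of chromosome 8 at -0.27, so these trends do not account for it. A different chromosome copy number in the cultures may account for it: the shift was present in each of 3 equal groups of chromosome 8 genes by expression, with the highest of the 3 medians at -0.23. The 3 medians ran from 0.15 to 0.25 on chromosome 14, -0.21 to -0.09 on chromosome 17, 0.07 to 0.25 on chromosome 4, 0.08 to 0.42 on chromosome 12 and -0.02 to 0.20 on chromosome 9, where copy number stays open. A change in transcription along the chromosome would look alike, and no DNA was measured. Whether such a difference arose by chance in culture or followed the hairpin cannot be separated, since it coincides with the groups.

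Reads shared with X-linked paralogs do not account for the rise of Y-linked genes, since the smallest difference between a Y-linked gene and its paralog (Ddx3y and Ddx3x) was 1.57 on the log2 scale (SE 0.07). A different share of male cells alone would raise these genes by a like factor, if all their reads came from male cells. Kdm5d and Uty rose by log2 fold changes that differ by 3.47 (SE 0.18). In shNT, however, Kdm5d stood at 0.33% of its paralog's level and Uty at 16.5%. Reads of the paralog could thus have lowered the rise of Uty, so the unequal rises cannot decide this. Of 8 genes known to escape X inactivation, 6 fell, Ddx3x rose and Jpx did not pass the test (2.7 ± 0.488 and 2 ± 0.572 CPM). Their median of -0.48 lay at percentile 4.9 of 10000 random X-linked lists (578 other X-linked genes, median -0.13), just under the bound of 5 that was set. That narrowly met the prediction written for different shares of male and female cells. A like rise of the Y-linked genes was also asked for and not seen. Since unequal rises cannot decide this, the question was left undecided. The 8 genes include the paralogs Kdm5c, Kdm6a, Eif2s3x and Ddx3x. Different shares of male and female cells stay open, with reads of paralogs at the low levels of shNT or with other differences between the cultures. Culture of origin and hairpin are confounded.

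The opposite change of HOX clusters was not removed by the same regression (HoxB median -3.76 after it). Smooth trends over all genes could hardly remove a change of this size in a few genes, so technical causes at these loci are not excluded. Cells of different positions of origin are a candidate explanation: of 33 tested positional transcription factors outside the HOX clusters, a list fixed before the values of its members were seen and without factors whose values had been seen, 15 changed by at least 2-fold (45.5%, 6 higher and 9 lower). That share lay at percentile 100 of 10000 random lists matched on expression, whose median was 15.2%. The random lists came from all other tested genes, not from other developmental regulators, so the excess does not single out position of origin. Without Evx2, which lies beside Hoxd13, 14 of 32 (43.8%) changed, also at percentile 100. The cultures of each group may differ in origin or in the cells that grew out, besides ARF. The labels name no separate cultures with which to part these, so an effect of ARF on these genes stays open.

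With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split called 9667 genes and the highest of the other splits 3 (1 of the 10 as large), and it gave 2460 changes of at least 2-fold against 3. The other splits put libraries of shARF and shNT into the same group, which widens the spread within groups. Few gene calls in them follow from that, so these counts do not show what equal groups would give. For the gene lists the real split gave 6 and the highest of the others also 6, so 2 of the 10 were as large. Each of the 9 other splits called between 2 and 6 lists with the preset correlation, with at most 3 genes changed. Their groups were unequal mixtures of shARF and shNT libraries. Part of the difference thus remained between them, and the lists called may carry it.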
